A study of Mus musculus with 32 samples.

How the data were processed

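RNA was measured by bulk RNA-seq in 32 libraries from mouse spinal cord, in 10 groups of 3 or 4 libraries set by treatment and time after injury. Per the labels, the mice were of strain C57BL/6J, the tissue was the cord segment around the lesion, it was snap-frozen, and total RNA was isolated with a kit for lipid-rich tissue. Libraries were sequenced as paired ends, per the labels' protocols. How Gsx1 and Nkx6.1 were delivered, the injury method, the sex of the mice and the batches of preparation and sequencing are not given in the sources used here.

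The authors deposited a table of raw read counts per gene symbol, with 1 column per library and no normalization. HISAT2, SAMtools, HTSeq and DESeq2 and the genome builds mm10 and GRCm38 are named in the submitters' processing notes, without version or role. The gene annotation, the strand setting of the counting, and how reads that match several genes were treated are not given in the sources used here. The deposited counts of overlapping genes, of antisense partners and of near-identical families (globin, histocompatibility, interferon-inducible Ifi and Gbp genes, protocadherins) are therefore uncertain as to which copy the reads came from. Each column was matched to its sample by the identifier in that sample's label, and 0 columns were left without a sample. The table held 23420 genes, of which 2504 had a count of 0 in all libraries, and no unassigned or total lines. Of the symbols, 21571 (92.1%) were present among RefSeq gene names. Coordinates were taken from the GENCODE annotation of GRCm38 and are 1-based.

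The total count per library ranged from 10.8 to 19.5 M (mega counts, median 14.6 M), and 17211 to 18085 genes were detected per library. The 10 most abundant genes took 4.65% to 8.73% of the counts. Across the 36 pairs of libraries within groups, Pearson's r of log2 CPM ranged from 0.9417 to 0.9877, and the lowest chi-square per degree of freedom between 2 libraries was 3.82, so no pair differed by as little as counting noise and none was treated as 1 library sequenced again. Same-numbered replicates were not treated as pairs. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples.

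Before the data were examined, the groups, the comparisons, the tests, the alternatives, the rule for named genes and 38 gene lists were fixed. Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, after edgeR's expression filter (minimum count 10, minimum total count 15), which left 16314 genes. All 10 groups entered 1 model without covariates, with 22 residual degrees of freedom, 4.4 prior degrees of freedom and a common biological coefficient of variation of 20.8%. The 15 comparisons were injury against sham at 3 and 35 days, Gsx1 against injured control at 3, 14 and 35 days, Nkx6.1 against injured control at 3 and 35 days, Gsx1 against Nkx6.1 at 3 and 35 days, 35 against 3 days in injured control and in sham cords, and 4 interactions of injury, Gsx1 or Nkx6.1 with time. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are edgeR's log2 fold changes with their standard errors (SE), and levels are CPM, counts scaled to a common library total with the TMM factors, as mean ± SD over the libraries of a group.

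The rule for named genes took Gsx1 and Nkx6-1 in every group. It took the 6 largest rises and 6 largest falls (4 for direct, time and interaction comparisons) among called genes with a mean CPM of at least 1, no overlap between the CPM of the groups, and no predicted or clone-based name. It also took up to 4 members with the smallest p of each gene list described. Some genes that this rule names are not reported here. With 3 libraries against 3, chance alone leaves a gene's groups without overlap in 10% of cases.

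Gene lists of cell types and pathways were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the 38 lists of each comparison. Camera compares a list with the other genes, and fry tests whether its genes move on balance in 1 direction. Called members were counted over all genes tested and adjusted over the list alone. With the estimated correlation the camera calls that held were reactive astrocyte at 3 days after injury, reactive astrocyte, macrophage and complement at 35 days, cell cycle over time in injured controls, endothelial cell over time in sham cords, and fibrotic scar for Gsx1 at 14 days. The lists held textbook markers, and markers of other tissues that a cord segment could hold (Schwann cell, sensory ganglion, skeletal muscle, blood).

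Correlations of fold changes and overlaps of calls were set beside 100 simulations of unchanged groups that shared the control libraries. Overlaps took as many genes of smallest p per direction as were called. Folds against a group at 0 were bounded with a floor of 3 counts over that group, and ratios against 1 to 3 counts carry a 95% counting interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. The test was run on simulated counts for 16314 genes, 100 changed per fold size. At 2-fold it recovered 72%, 77% and 74% for injury, Gsx1 and Nkx6.1 at 3 days and 80% for Gsx1 at 35 days. At 4-fold it was 96%, 95%, 96% and 98%. Power may be lower in the data, where sex and tissue differ.

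The alternatives were no filter and a strict one (CPM of at least 1 in 3 libraries), DESeq2 (1.42.0), limma-voom with quality weights, RLE and upper-quartile factors, a fit of the compared groups only, a replicate block, Xist as a covariate, an adjusted p under 0.01, a fold of at least 2, and each library left out in turn. After seeing the data, 4 were added. Some left out the 2 mixed-sex libraries (Xist over 100 and Ddx3y over 10 CPM) or kept the 25 low-Xist ones only. Others took log2 CPM of H2-Bl and Rpl29, or the level of Trim12a (over or under 1 CPM), as covariates. Other splits of the compared libraries were refitted for 11 comparisons.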

Results

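Gene expression was measured in the spinal cord of mice after a sham operation or a spinal cord injury, and the injured cords carried a control treatment, Gsx1 or Nkx6.1. Gsx1 and Nkx6.1 are homeobox transcription factors of the developing spinal cord, and the title of the series concerns Gsx1 and the recovery of locomotion. Sham cords were taken at 3 and 35 days (n = 3 each) and injured control cords at 3, 14 and 35 days (n = 3, 3 and 4). Gsx1 cords were taken at 3, 14 and 35 days (n = 3, 3 and 4) and Nkx6.1 cords at 3 and 35 days (n = 3 each). Mean total counts per group ranged from 12.8 ± 0.531 M (mega counts; SD, n = 3, sham at 35 days) to 16.8 ± 0.439 M (SD, n = 3, Gsx1 at 3 days). The leading principal component of log2 CPM held 45.4% of the variance. Sham libraries lay at a mean of -68.6 ± 3.84 (SD, n = 3) at 3 days and -85.3 ± 5.72 (SD, n = 3) at 35 days. Injured control libraries lay at 45.8 ± 15.5 (SD, n = 3), 8.84 ± 14.6 (SD, n = 3) and 14.5 ± 27.5 (SD, n = 4) at 3, 14 and 35 days. Gsx1 libraries lay at 47 ± 20.6 (SD, n = 3), -3.58 ± 10.8 (SD, n = 3) and -16.7 ± 6.74 (SD, n = 4). Nkx6.1 libraries lay at 78.7 ± 34.5 (SD, n = 3) and -20.1 ± 29.7 (SD, n = 3) at 3 and 35 days.

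**Figure D1:**
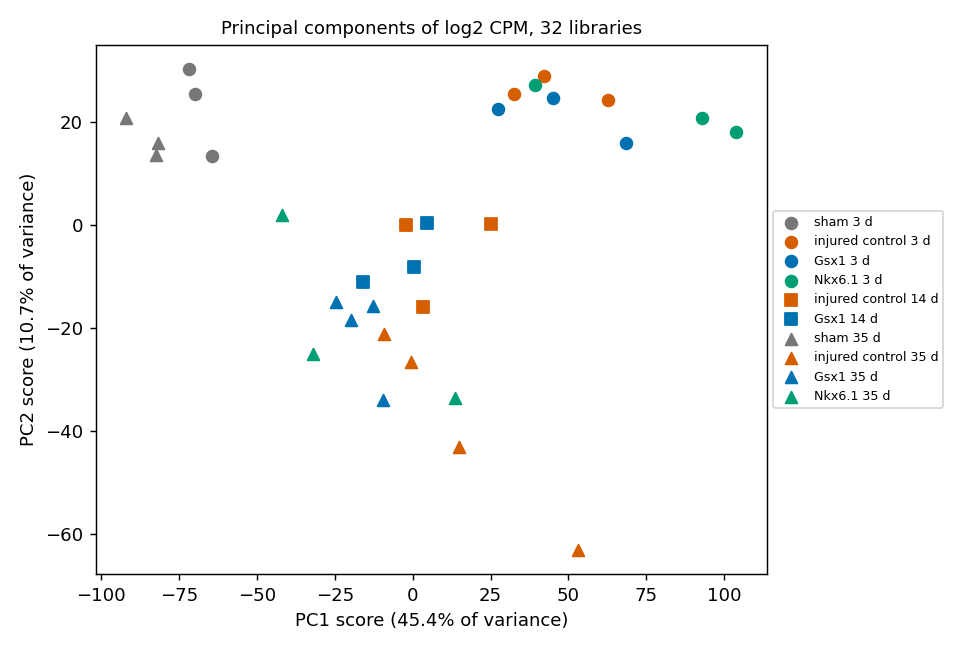
Principal components 1 and 2 of log2 CPM, with 1 point per library coloured by group. Component 1 (45.4% of the variance) separated the 6 sham libraries from the injured ones, and component 2 held 10.7%.

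Xist, the transcript of the inactive X chromosome, and the Y-linked gene Ddx3y marked the sex of the tissue in each library. Xist exceeded 100 CPM in 7 libraries. At 3 days they were sham replicates 1 and 2 and injured control replicate 1. At 35 days they were sham replicate 3, injured control replicates 1 and 4 and Nkx6.1 replicate 2. The other 25 were low in Xist, and 0 Gsx1 libraries were high (replicate 2 at 3 days had 17.3 CPM). Of the 7, sham replicate 1 at 3 days and injured control replicate 4 at 35 days had Ddx3y over 10 CPM (19.1 and 32.1). Sex and group were therefore unevenly mixed at 3 and 35 days.

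**Figure D2:**
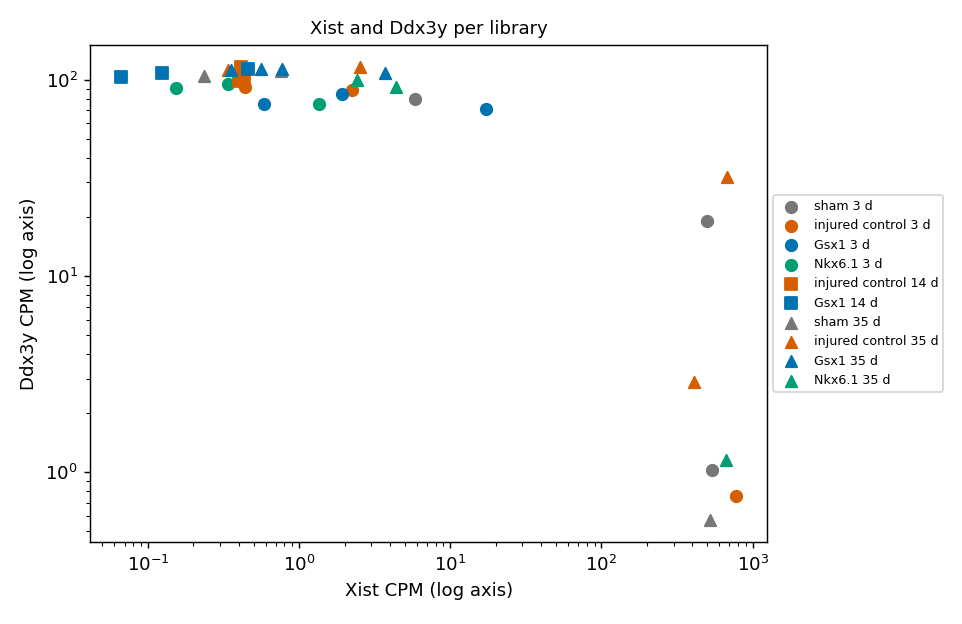
Xist against Ddx3y in CPM on log axes, with 1 point per library coloured by group. Of 32 libraries, 7 had Xist over 100 CPM, and 2 of these also held Ddx3y at 19.1 and 32.1 CPM.

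Transcripts of the delivered factors were compared in every group, since they could check the labels. Gsx1 (chromosome 5, 147188696 to 147190947, plus strand, GRCm38) had 0 to 10 counts per library. Its level was 0.156 ± 0.0881 CPM (SD, n = 3) in Gsx1 libraries against 0.323 ± 0.105 (SD, n = 3) in injured controls at 3 days. It was 0.424 ± 0.247 (SD, n = 3) against 0.164 ± 0.0677 (SD, n = 3) at 14 days, and 0.304 ± 0.174 (SD, n = 4) against 0.152 ± 0.145 (SD, n = 4) at 35 days. The edgeR log2 fold changes without the expression filter were -1.02 ± 0.88 (SE, 95% interval -2.75 to 0.71), 1.29 ± 0.88 (SE, -0.44 to 3.01) and 0.95 ± 0.80 (SE, -0.62 to 2.52), with Benjamini-Hochberg adjusted p of 1, 1 and 0.578. Nkx6-1 (chromosome 5, 101658139 to 101664996, minus strand) stood at 5.15 ± 1.34 CPM (SD, n = 3) in Nkx6.1 libraries against 7.85 ± 1.02 (SD, n = 3) in controls at 3 days (log2 fold change -0.60 ± 0.23 SE, edgeR adjusted p = 0.176). At 35 days it stood at 9.55 ± 2.45 (SD, n = 3) against 11 ± 1.26 (SD, n = 4), with a log2 fold change of -0.20 ± 0.21 (SE, edgeR adjusted p = 0.679). In Gsx1 libraries the log2 fold change of Nkx6-1 was -0.04 ± 0.23, 0.33 ± 0.23 and -0.15 ± 0.19 (SE) at 3, 14 and 35 days, with edgeR adjusted p of 1, 0.987 and 0.673. The value at 3 days turned to 0.07, 0.09 and 0.02 without injured control replicate 2, Gsx1 replicate 1 and Gsx1 replicate 2. Nkx6-1 had 47 to 250 counts per library, and without the filter its 95% interval in Nkx6.1 libraries was -1.05 to -0.14 at 3 days and -0.58 to 0.24 at 35 days. A rise of the counted Nkx6-1 transcript was therefore not seen. At the few counts of Gsx1 the intervals left log2 rises of up to 0.71, 3.01 and 2.52 open at 3, 14 and 35 days, and groups carry the names of their labels. A transgene without the untranslated regions of the mouse gene, or of another species, would be counted in part or not at all.

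**Figure D3:**
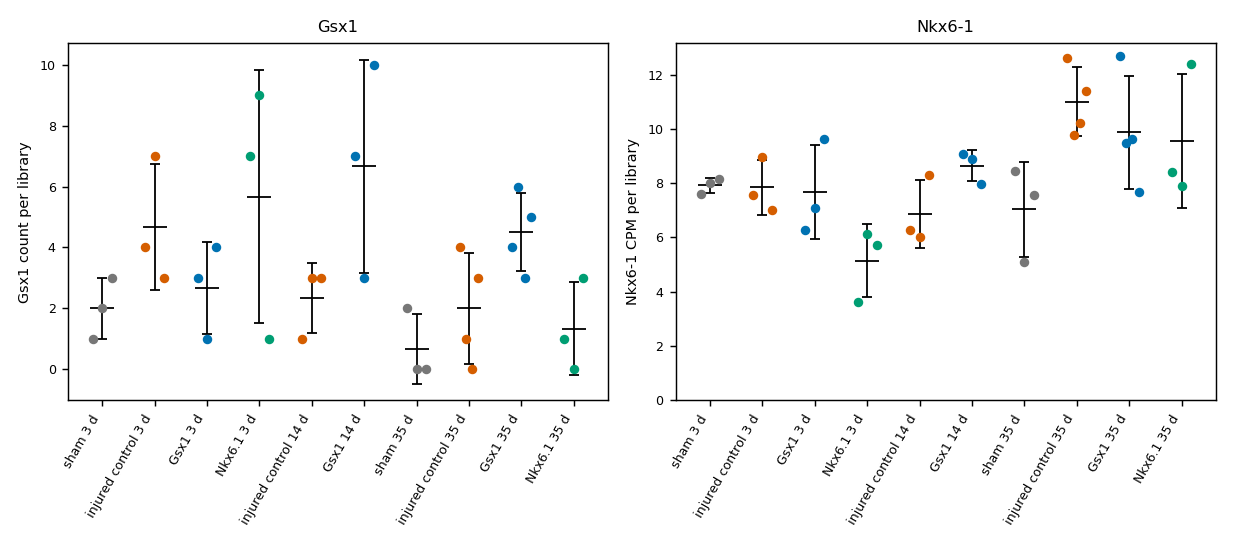
Gsx1 (counts) and Nkx6-1 (CPM) in each group, with points for libraries and bars for mean ± SD. Gsx1 stayed at or under 10 counts in every library, and Nkx6-1 group means lay between 5.15 and 11 CPM.

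Injured cords with the control treatment were compared with sham cords, whose labels name no such treatment. Changes by the lesion and by the control treatment cannot be told apart here, and both are meant by injury below. At 3 days, macrophage, complement, cytokine, cell cycle and reactive astrocyte genes rose and neuronal genes fell. Of 20 macrophage and phagocyte genes 18 rose (20 adjusted over the list alone). Gpnmb, a glycoprotein of phagocytes, went from 5.58 ± 2.4 CPM (SD, n = 3) in sham to 593 ± 216 (SD, n = 3), Spp1 (osteopontin) had a log2 fold change of 4.71 ± 0.42 (SE), Cd68 of 4.57 ± 0.45 (SE) and Lyz2 (lysozyme) of 4.43 ± 0.47 (SE). All 12 complement genes rose, among them the receptor C3ar1 by 35.8-fold and C4b by 5.36-fold, as did 14 of 15 cytokines and chemokines (14 adjusted over the list alone). The monocyte chemokine Ccl2 rose to 22.6 ± 10.5 CPM (SD, n = 3) from 0.534 ± 0.0485 (SD, n = 3), and Ccl7 by a count ratio of 230 (95% counting interval 63.2 to 1900). All 16 reactive astrocyte genes rose, including Vim (vimentin) at 15.6-fold, Cd109 at 16.6-fold and Tgm1, from 0.511 ± 0.0878 to 106 ± 50.4 CPM (SD, n = 3 each). All 20 cell cycle genes rose, including Ccnb1 (cyclin B1) by 5.48 ± 0.60 and the centromere protein Cenpf by 4.52 ± 0.47 on the log2 scale (SE). In edgeR's test these genes had adjusted p of 5.74e-06 or less. By camera with Benjamini-Hochberg adjustment the lists had median log2 fold changes and adjusted p of 3.25 and 4e-23 (macrophage), 2.67 and 5.66e-13 (complement), 4.34 and 9.9e-10 (cytokine, 3.88 with the member at 0 in a group set to its bound), 3.13 and 9.33e-25 (reactive astrocyte) and 3.27 and 5.27e-24 (cell cycle). With an estimated correlation their adjusted p was 0.0535, 0.0631, 0.0535, 0.0282 and 0.0535.

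Neuronal genes moved the other way. Of 16 pan-neuronal genes 13 fell (16 adjusted over the list alone): the synaptic gene Snap25 went from 2640 ± 25.9 to 1230 ± 132 CPM and Rbfox3 (NeuN) from 184 ± 4.14 to 96 ± 13 CPM (SD, n = 3 each). Of 15 glutamatergic genes 13 fell (14 alone), such as the receptor subunits Grin2b at -1.45 ± 0.26 and Gria4 at -0.98 ± 0.21 (log2, SE). Of 16 GABAergic and glycinergic genes 10 fell (13 alone), such as Glra1 and Glrb of the glycine receptor at -1.46 ± 0.30 and -1.11 ± 0.24 (log2, SE). Of 9 cholinergic genes 7 fell (7 alone), such as Chrna4 at -1.36 ± 0.28 (log2, SE). Of 15 cholesterol synthesis genes 11 fell (14 alone), with Fdft1 (squalene synthase) at -0.52 ± 0.09 and Insig1 at -1.03 ± 0.24 (log2, SE), and 5 of the 15 fell without the 2 libraries of mixed sex. Camera adjusted p for these 5 lists were 1.12e-06, 4.69e-06, 3.38e-05, 0.000434 and 8.72e-06. Adjusted p with an estimated correlation was 0.359 for pan-neuronal, glutamatergic, cholinergic and cholesterol genes and 0.407 for GABAergic genes.

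The largest rises among genes with separate groups included genes absent from the 3 sham libraries. Atp6v0d2, a subunit of the proton pump of osteoclasts and macrophages, was at least 66.8-fold higher, the chemokine Ccl5 at least 45.3-fold and Slamf7 at least 39.7-fold. The ratio was 301 for the interleukin 1 antagonist Il1rn (95% counting interval 83 to 2490) and 361 for coagulation factor F7 (64.3 to 14300). Tnnc2, a troponin of fast skeletal muscle, was at least 64.2-fold higher on average (5.04 ± 7.97 CPM, SD, n = 3), and its edgeR call (adjusted p = 0.0242) was lost without injured control replicate 3 (0.303) and without sham replicate 1, 2 or 3 (0.0663, 0.0664 and 0.0702). Injured control replicate 3 held skeletal muscle genes at a mean log2 CPM of 4.41, against 1.34 and -0.92 in replicates 1 and 2. The largest falls were Slc17a7 (vesicular glutamate transporter VGLUT1), from 12.4 ± 6.71 to 1.12 ± 0.208 CPM (SD, n = 3 each), then Fbxo40, Aqp6, the galanin receptor Galr1, the Notch target Hes5 and Colq, with log2 fold changes of -2.57, -2.49, -2.46, -2.04 and -2.01 and edgeR adjusted p between 0.000288 and 0.00605 over the 6.

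Other lists rose in part or went both ways at 3 days. All 20 type I interferon genes rose (Irf9 4.22-fold, Bst2 15-fold), as did 12 of 14 antigen presentation genes (13 alone). Rises were also called for 15 of 18 fibrotic scar genes (16 alone; Fn1 7.58-fold, Thbs2 3.86-fold), 8 of 12 microglia genes (Cx3cr1 3.17-fold), 9 of 15 regeneration-associated genes (Atf3 27.7-fold, Sprr1a 23.5-fold, with 1 fall) and 8 of 10 endothelial genes (Pecam1 2.51-fold). These 6 lists had camera adjusted p of 1.82e-09, 2.46e-07, 9.05e-06, 2.5e-06, 0.000215 and 0.0022. Adjusted p with an estimated correlation was 0.359, 0.359, 0.407, 0.359, 0.256 and 0.359. Camera also called neutrophil genes higher (3 of 11 rose, adjusted p = 0.0463, 0.674 with an estimated correlation) and pericyte genes higher (3 of 8 rose, 4 alone, 0.047, 0.407 with an estimated correlation). It called dorsal spinal transcription factors lower (2 of 11 fell, 5 alone, 0.00631, 0.462 with an estimated correlation) and axon guidance genes lower (4 of 30 rose and 9 fell, 0.0118, 0.501 with an estimated correlation). Neural stem genes were not called as a list (3 of 12 rose, 1 fell, camera adjusted p = 0.142), while the progenitor markers Nes (nestin) and Fabp7 rose 5.01-fold and 4.47-fold and Sox2 1.48-fold. Astrocyte genes (3 of 12 rose, 1 fell; Aldh1l1 2.05-fold, Aqp4 1.91-fold), Notch pathway genes (7 of 23 rose, 3 fell; Notch1 1.8-fold), oligodendrocyte precursor genes (2 of 10 rose; Gpr17 2.45-fold) had camera adjusted p of 0.703, 0.305 and 0.295. For chondroitin sulfate proteoglycan genes (6 of 15 rose, 2 fell; Tnc 11.3-fold, Ncan 2.33-fold), immature neuron genes (2 of 7 rose, 2 fell; Tubb2b 2.09-fold) and stress genes (2 of 13 rose; Junb 3.32-fold) it was 0.295, 0.958 and 0.378. The remaining 11 lists were not called either, with camera adjusted p of 0.295 or more. They were ventral spinal transcription factors (1 of 13 rose, 1 fell), neurotrophic factors (5 of 17 rose, 3 fell), T and NK cell (1 of 10 rose) and B and plasma cell genes (0 of 6). They were also oligodendrocyte and myelin (1 of 13 rose, 2 fell), ependymal cell (0 of 12), Schwann cell (3 of 10 rose), sensory ganglion (1 of 4 fell), skeletal muscle (5 of 11 rose, 1 fell), red blood cell (0 of 4) and sex-linked genes (0 of 5).

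In all, edgeR called 5788 of 16314 genes at 3 days (3174 higher, 2614 lower), of which 2163 changed at least 2-fold (1712 higher, 451 lower). The count was 3530 without injured control replicate 1 and 1753 with the low-Xist libraries only, which leaves 1 sham library and ends the calls of Snap25, Rbfox3, Glra1, Fdft1, Insig1, Aqp4, Slamf7, Slc17a7, Fbxo40, Hes5 and Colq (edgeR adjusted p 0.0532 to 0.149). With these libraries the members that fell numbered 2 of 16 pan-neuronal, 2 of 15 glutamatergic, 3 of 16 GABAergic and glycinergic, 2 of 9 cholinergic, 0 of 15 cholesterol synthesis and 0 of 30 axon guidance genes. Those that rose numbered 4 of 18 fibrotic scar, 8 of 15 cytokine, 11 of 20 type I interferon, 6 of 14 antigen presentation and 2 of 10 endothelial genes. The 5 rises of skeletal muscle genes were lost without the 2 libraries of mixed sex.

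At 35 days the injured control cords kept raised phagocyte, complement, astrocyte and collagen genes. Of 20 macrophage genes 17 rose (18 adjusted over the list alone): Lyz2 went from 14.3 ± 4.78 CPM (SD, n = 3) to 1020 ± 380 (SD, n = 4), Gpnmb rose 207-fold and the integrin Itgax 151-fold. Of 12 complement genes 11 rose (11 alone; C4b 8.66-fold, the C1 inhibitor Serping1 26.8-fold), and all 16 reactive astrocyte genes rose (Vim 13.6-fold, the oncostatin M receptor Osmr 9.32-fold). All 18 fibrotic scar genes rose, with Col1a1 (collagen I) from 10.6 ± 4.51 (SD, n = 3) to 243 ± 217 CPM (SD, n = 4) and Fn1 (fibronectin) at 8.56-fold. All 10 T and NK cell genes rose: Cd3e of the T cell receptor was at least 17.8-fold higher, and Cd8a had a ratio of 70.3 (95% counting interval 12.3 to 2800). All 15 cholesterol synthesis genes fell, such as Fdps at -1.19 ± 0.17 and Cyp51 at -1.07 ± 0.16 (log2, SE). With the low-Xist libraries only, 1 of 13 T and NK cell genes tested rose and 9 of 15 cholesterol synthesis genes fell. For macrophage, complement, reactive astrocyte, fibrotic scar, T and NK cell and cholesterol lists the medians were 2.94, 3.28, 3.11, 3.03, 4.76 (4.36 with members at 0 set to their bound) and -1.07, with camera adjusted p of 7.59e-26, 3.36e-18, 7.59e-26, 7.19e-10, 0.000129 and 9.79e-16. Adjusted p with an estimated correlation was 0.0453, 0.0364, 0.0268, 0.282, 0.251 and 0.0857.

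Neuronal genes were lower at 35 days as well. In the pan-neuronal list 11 of 16 fell (13 alone; Snap25 -0.96 ± 0.24, log2, SE) and in the glutamatergic list 9 of 15 (9 alone; Gria4 -0.89 ± 0.19). In the GABAergic and glycinergic list 12 of 16 (12 fell and 1 rose alone; Gabra5 -1.22 ± 0.27) and in the cholinergic list 5 of 9 (5 alone). Camera adjusted p was 8.11e-06, 0.000122, 6.71e-05 and 0.00591, and adjusted p with an estimated correlation was 0.369, 0.369, 0.377 and 0.378. The calls of Snap25 and Gria4 were lost when only the compared groups were fitted, and those of Snap25, Gria4 and Gabra5 with the low-Xist libraries only. Injured control replicate 4 had a pan-neuronal mean of 8.26 log2 CPM, against 9.07 to 9.16 in the other 3 and 9.6 to 9.61 in sham libraries. Without it the medians of the pan-neuronal, glutamatergic, GABAergic and cholinergic lists went from -0.66, -0.69, -0.83 and -0.77 to -0.48, -0.45, -0.58 and -0.56. Without the libraries of mixed sex, which include it, 4, 5, 2 and 0 of their members fell. With H2-Bl and Rpl29 as covariates 4, 2, 2 and 0 fell, and with the low-Xist libraries 0 in each list. Camera also called 10 lists higher and 2 lower. Higher were cell cycle (15 of 20 rose, 17 alone; Top2a 7.58-fold), antigen presentation (14 of 14), cytokines (12 of 15; Tgfb1 7.28-fold; median 4.7, 3.68 with bounds), type I interferon (9 of 20, 13 alone; Bst2 13.1-fold; mean log2 CPM 4.14 in injured control replicate 4 and 2.92 to 3.11 in the other 3), and microglia genes (9 of 12). So were regeneration-associated (9 of 15 rose, 1 fell; Atf3 29.8-fold), endothelial (8 of 10), ependymal (7 of 12; Foxj1 1.52-fold), neutrophil (1 of 11) and stress genes (7 of 13; Junb 3.12-fold), with adjusted p from 7.4e-11 to 0.0297. Lower were axon guidance genes (4 of 30 rose, 12 fell, adjusted p = 0.0189) and myelin genes (4 of 13 fell; Fa2h -0.72 ± 0.17; adjusted p = 0.0314). With an estimated correlation the adjusted p of these 12 lists ranged from 0.0857 to 0.522. With H2-Bl and Rpl29 as covariates 8 of 20 cell cycle, 5 of 20 type I interferon and 5 of 10 endothelial genes rose, and 3 of 30 axon guidance and 1 of 13 myelin genes fell. Without the 2 libraries of mixed sex 5 endothelial, 4 ependymal and 3 stress genes rose, and 0 axon guidance and 1 myelin gene fell. With the low-Xist libraries only, 1 cell cycle, 1 type I interferon, 7 cytokine, 3 regeneration-associated, 3 endothelial, 2 ependymal and 1 stress gene rose, and 0 axon guidance or myelin genes fell. Lists that camera did not call included neural stem genes (6 of 12 rose, 1 fell; Nes 4.21-fold, Pax6 2.02-fold), Schwann cell genes (5 of 10 rose, 1 fell), oligodendrocyte precursor genes (2 of 10 rose, 1 fell; Olig2 -0.57 ± 0.09) and neurotrophic factors (3 of 17 rose, 1 fell; Igf1 11.4-fold). Immature neuron genes (1 of 7 rose; Sox4 2.5-fold) and skeletal muscle genes (0 of 11) were not called either. The Schwann cell gene Egr2 had a log2 fold change of 4.92 ± 0.80 (SE, edgeR adjusted p = 4.81e-05).

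The largest rises at 35 days were again of genes absent or nearly absent in sham cords. The macrophage elastase Mmp12 (chromosome 9, 7344381 to 7369499, plus strand) was at least 226-fold higher, Wfdc17 at least 69.6-fold and Cd200r4 at least 67.1-fold, and the ratio was 517 for Cst7 (95% counting interval 177 to 2510) and 581 for Ms4a7 (104 to 23000). Wisp2 went from 0.135 ± 0.171 (SD, n = 3) to 67.9 ± 41.5 CPM (SD, n = 4). Of the 6 largest falls, Lgr6 (chromosome 1, 134983301 to 135105276, minus strand) kept its call whichever library was left out (log2 fold change -1.82 ± 0.35 SE, edgeR adjusted p = 0.000291). Cml5 (-2.13 ± 0.60) lost it without sham replicate 1 (adjusted p = 0.0558). H2-Bl lost it without sham replicate 1 or 3 or injured control replicate 1 or 4 (adjusted p 0.0665 to 0.112). Opn4 lost it without 6 of the 7 libraries (all but injured control replicate 3, 0.0534 to 0.0932). Ghsr lost it without sham replicate 3 or injured control replicate 1 or 4 (0.0753 to 0.091) and Adrb3 without sham replicate 1 or 2 or injured control replicate 4 (0.0636 to 0.169). Nkx6-1 rose by 0.64 ± 0.21 (log2, SE), from 7.03 ± 1.74 (SD, n = 3) to 11 ± 1.26 CPM (SD, n = 4, edgeR adjusted p = 0.0218). That call was lost without sham replicate 2 (adjusted p = 0.14) or injured control replicate 1 (0.055) or 4 (0.0538). At 3 days its log2 fold change had been -0.01 ± 0.23 (SE, edgeR adjusted p = 0.977), and it turned positive, to between 0.01 and 0.08, without sham replicate 2 or 3 or injured control replicate 1 or 3.

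EdgeR called 6009 of 16314 genes at 35 days (3481 higher, 2528 lower), of which 2084 changed at least 2-fold (1962 higher, 122 lower). The count was 3599 without sham replicate 3, 3453 without injured control replicate 4, 2195 with the compared groups only, 3178 without the 2 libraries of mixed sex, 1281 with the low-Xist libraries only and 3666 with H2-Bl and Rpl29 as covariates. Of the genes higher at 3 days, 2193 were also higher at 35 days (677.3 for independent lists), 1665 were lower at both times (405.1 for independent lists), and 10 changed in opposite directions (4 and 6). The sham libraries of the 2 times differed, so these comparisons share no control.

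**Figure D4:**
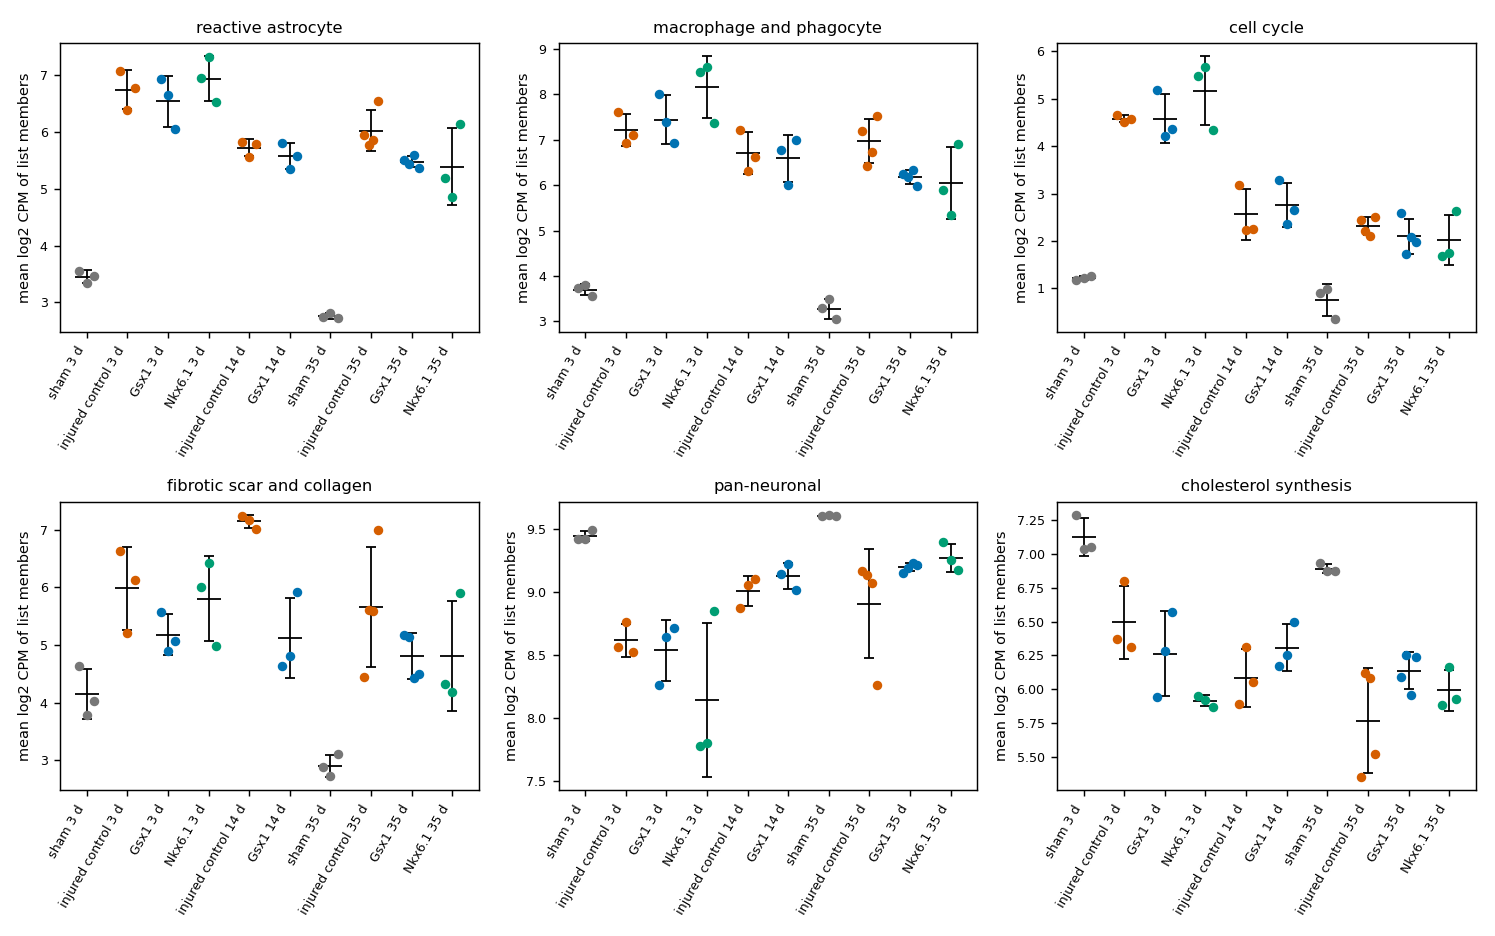
Mean log2 CPM of 6 gene lists in each group, with points for libraries and bars for mean ± SD. Macrophage genes lay at 3.7 ± 0.12 (SD, n = 3) in sham and 7.22 ± 0.35 (SD, n = 3) in injured control cords at 3 days, and at 3.28 ± 0.22 (SD, n = 3) and 6.97 ± 0.49 (SD, n = 4) at 35 days.

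The injured control cords were compared between 35 and 3 days to follow the lesion over time. Proliferation genes dropped: 19 of 20 cell cycle genes fell (19 adjusted over the list alone, median log2 fold change -2.42, camera adjusted p = 3.46e-33, 0.0341 with an estimated correlation). Type I interferon genes (8 of 20 fell, 18 alone), cholesterol synthesis genes (10 of 15 fell, 12 alone) and endothelial genes (5 of 10 fell, 6 alone) were lower by camera at adjusted p of 3.31e-07, 4.37e-11 and 1.77e-07. Adjusted p with an estimated correlation was 0.476, 0.281 and 0.217. Ependymal genes (5 of 12 rose, 5 alone) and T and NK cell genes (3 of 10 rose, 8 alone) were higher at camera adjusted p of 0.000116 and 0.000476, both 0.281 with an estimated correlation. Among single genes, the apolipoprotein Apoc4 went from 0.197 ± 0.289 (SD, n = 3) to 8.43 ± 6.02 CPM (SD, n = 4) and Igfbpl1 from 0.591 ± 0.274 (SD, n = 3) to 21.9 ± 18.1 (SD, n = 4). Myoc (5.15 ± 1.40) and Trim12a (5.41 ± 1.67) had similar log2 fold changes. Their calls were lost without injured control replicate 1, 2 or 3 at 3 days (edgeR adjusted p 0.0758, 0.0602 and 0.0773 for Myoc, 0.13, 0.0974 and 0.112 for Trim12a). That of Trim12a was also lost without replicate 1 or 4 at 35 days (0.0521 and 0.0588). The interferon-inducible genes Gbp1 and Ifi44l and the histidine ammonia-lyase gene Hal had log2 fold changes of -7.43, -7.09 and -7.49, and Ifi202b was higher at 3 days by a ratio of 827 (95% counting interval 283 to 4010). Those 4 calls were lost with limma-voom and with the low-Xist libraries only. Trim12a, Ifi202b and Hal were among 14 autosomal genes that lay at separate levels within groups. Trim12a was at its higher level in 20 of 32 libraries, with 0 of 3 injured control libraries at 3 days and 4 of 4 at 35 days. EdgeR called 1797 genes (823 higher, 974 lower), 797 without injured control replicate 1 and 1089 without replicate 3 at 3 days, 457 with the compared groups only, 331 with the low-Xist libraries only and 3202 by limma-voom. Of the genes higher after injury at 3 days, 681 fell between 3 and 35 days, and of those lower after injury 274 rose. Independent lists give 189.5 and 131.9. Equally long lists simulated without effects gave 546.6 and 479.1, so an untested part of these overlaps may come from the shared 3-day controls.

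In sham cords, edgeR called 1 gene between 35 and 3 days, with 1171 at an unadjusted p under 0.05 (816 by chance), 41 by DESeq2, 426 by limma-voom, 633 by edgeR on the compared groups only, and 12 with the level of Trim12a as a covariate. Vwf (chromosome 6, 125546774 to 125686679, plus strand), the von Willebrand factor of endothelial cells, went from 86.1 ± 5.88 to 15.7 ± 3.72 CPM (SD, n = 3 each, log2 fold change -2.45 ± 0.40 SE, edgeR adjusted p = 0.0239). This call was lost without sham replicate 1 or 3 at 3 days (0.0677 and 0.105) or replicate 1, 2 or 3 at 35 days (0.402, 0.45 and 0.0973), and 4 genes were called without replicate 2 at 3 days. The endothelial list was lower (1 of 10 fell, 7 alone, median -0.68, camera adjusted p = 6.12e-15, 0.0239 with an estimated correlation). Fibrotic scar genes (0 of 18 over all genes, 7 fell alone, median -1.3) and skeletal muscle genes (0 of 11, 3 rose alone, median 3.65) had camera adjusted p of 4.53e-12 and 1.15e-07, both 0.266 with an estimated correlation.

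Whether the injury response itself differed between 35 and 3 days was tested as an interaction. The effect of injury was larger at 35 days for the extracellular matrix gene Fmod (fibromodulin, 3.85 ± 0.48), Igf2 (4.33 ± 0.86), Clec3b (4.15 ± 0.93) and the transporter Slc47a1 (7.10 ± 1.42, log2, SE). It was smaller for the mitotic genes Cep55 (-5.07 ± 0.94), Cdca5 (-4.57 ± 1.05), Kif14 (-3.74 ± 0.85) and Ckap2 (-3.38 ± 0.58, log2, SE), all with edgeR adjusted p between 0.000256 and 0.0494. EdgeR called 59 genes (29 higher, 30 lower, 1563 at an unadjusted p under 0.05), against 230 with DESeq2, 565 with limma-voom, 32 with the compared groups only, 18 with Xist as a covariate, 10 without the 2 libraries of mixed sex, 1 with the low-Xist libraries only, 169 with H2-Bl and Rpl29 as covariates and 108 with the level of Trim12a as a covariate. Leaving out sham replicate 1, 2 or 3 at 3 days gave 20, 27 and 27, and injured control replicate 1, 2 or 3 at 3 days 20, 28 and 26. Without sham replicate 1, 2 or 3 at 35 days it was 12, 15 and 14, and without injured control replicate 1 or 2 at 35 days 99 and 89. Fmod kept its call in every alternative, and Ckap2 in all but the low-Xist libraries. The other 6 lost theirs without at least 1 library (edgeR adjusted p 0.0516 to 0.178), Cep55 without sham replicate 1 at 35 days (0.178). The cell cycle list was lower (1 of 20 fell, 14 alone, median -1.68, camera adjusted p = 4.34e-21, 0.213 with an estimated correlation).

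Gsx1 cords were compared with injured controls at each time, to show what Gsx1 added to the injury. At 3 days no gene passed. Collagen genes Col1a1 (-1.46 ± 0.68) and Col5a2 (-0.92 ± 0.41) and microglia genes Tmem119 (0.56 ± 0.21) and P2ry12 (0.52 ± 0.20, log2, SE) had the smallest p of their lists, each with an edgeR adjusted p of 1. Fibrotic scar genes had a median of -0.80 and microglia genes of 0.47 (0 of 18 and 0 of 12 called, also adjusted over the list alone). Camera adjusted p was 9.41e-12 and 7.51e-11, 0.395 and 0.273 with an estimated correlation. Skeletal muscle genes (0 of 11 called, 8 fell adjusted over the list alone, median -4.42) and Schwann cell genes (0 of 10, 5 fell alone, median -1.04) were lower at camera adjusted p of 6.31e-10 and 1.23e-09, 0.273 and 0.243 with an estimated correlation. These were the lists in which injured control replicate 3 stood at 4.41 and 6.56 mean log2 CPM, against -0.44 ± 0.25 and 4.58 ± 0.21 (SD, n = 3) in Gsx1 libraries. Camera called 10 of 38 lists in all, and 0 with an estimated correlation. EdgeR, DESeq2 and limma-voom called 0 genes, with 338 at an unadjusted p under 0.05 in edgeR's test, where chance gives 816.

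At 14 days, collagen genes were lower in Gsx1 cords as a group. Col6a2, a collagen VI chain, stood at 32.7 ± 21.8 CPM against 146 ± 17.1 in controls, Col6a1 at 48.2 ± 27.4 against 168 ± 18.8 and Col5a1 at 32.9 ± 7.88 against 121 ± 13.5 (SD, n = 3 each). Their log2 fold changes were -2.16 ± 0.48, -1.80 ± 0.42 and -1.88 ± 0.45 (SE). Of 18 fibrotic scar genes 0 fell over all genes tested (edgeR adjusted p 0.171, 0.212 and 0.223 for these 3) and 17 fell adjusted over the list alone. Their median was -1.84, with a camera adjusted p of 2.33e-36, 0.0363 with an estimated correlation and 0.0494 by fry. The mean log2 CPM of the list was 5.12 ± 0.69 against 7.14 ± 0.12 (SD, n = 3 each), with no overlap. Schwann cell genes moved in the same direction (0 of 10, median -0.75, camera adjusted p = 0.000454, 0.403 with an estimated correlation). Myelin genes had a median of 0.39 (0 of 13; Mag 0.36 ± 0.13, Mog 0.43 ± 0.16, log2, SE) and astrocyte genes of 0.21 (0 of 12; S100b 0.51 ± 0.26), with camera adjusted p of 6.21e-10 and 0.0011, 0.262 and 0.375 with an estimated correlation. Red blood cell genes were higher (0 of 4, 2 rose alone, median 1.85, camera adjusted p = 0.000574, 0.375 with an estimated correlation), with beta-globin, listed as Beta-s, at 1880 ± 939 against 378 ± 215 CPM (SD, n = 3 each). EdgeR called 0 genes (960 at an unadjusted p under 0.05, smallest adjusted p = 0.0773; 816 by chance, 575 without Gsx1 replicate 1, 599 without injured control replicate 1, 1613 with the compared groups only and 2463 by limma-voom), DESeq2 47 and limma-voom 423. Without Gsx1 replicate 3 edgeR called 11 genes, among them Col6a2 (-2.85, adjusted p = 0.0372) and Col6a1 (-2.37, 0.0472), 4 without injured control replicate 2 and 1 without replicate 3. The change of the Gsx1 effect from 3 to 14 days was called for 0 genes (309 at an unadjusted p under 0.05 in edgeR, 2 by DESeq2, 2 by edgeR without injured control replicate 2 at 14 days).

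At 35 days, no gene passed in Gsx1 cords, and levels of phagocyte and complement genes lay below those of the controls. Lyz2 stood at 416 ± 50.3 against 1020 ± 380 CPM, the lysosomal protease Ctsd at 1610 ± 135 against 3380 ± 1580, Apoe at 6370 ± 1410 against 12600 ± 5850, and C1qb of the complement at 173 ± 30.4 against 386 ± 211 (SD, n = 4 each). Ms4a7, C1qa and Serping1 had log2 fold changes of -1.41 ± 0.39, -1.12 ± 0.33 and -1.25 ± 0.36 (SE), and the edgeR adjusted p of all 7 was 0.194. Of 20 macrophage genes 10 fell adjusted over the list alone (median -0.93), of 12 complement genes 4 (-0.76), and of 18 fibrotic scar genes 6 (-1.14; Col6a2 -1.50 ± 0.41, Col1a1 -1.75 ± 0.59). Of 16 reactive astrocyte genes 5 fell on that count (-0.60; Gfap -0.58 ± 0.21, Sox9 -0.44 ± 0.14), and of 14 antigen presentation genes 3 (-0.93). Of 10 T and NK cell genes 1 fell (-1.14; Cd8b1 -3.11 ± 0.83), of 13 stress genes 2 (-0.38; Fosb -1.09 ± 0.35, log2, SE) and of 12 microglia genes 0 (median -0.39). Neuronal lists lay higher, without any member passing: GABAergic and glycinergic (median 0.47; Gad2 0.71 ± 0.33, Gabra5 0.59 ± 0.26), glutamatergic (0.33; Gria4 0.50 ± 0.18) and pan-neuronal (0.23). So did cholesterol synthesis (0.36; Sc5d 0.44 ± 0.18). Pan-neuronal means were 9.15 to 9.23 log2 CPM in Gsx1 libraries, 8.26 in control replicate 4 and 9.07 to 9.16 in the other 3. Gsx1 replicate 3 was lowest of its group for GABAergic (5.85, others 6.46 to 6.51) and glutamatergic genes (5.3, others 5.85 to 5.91). Control replicates 1 and 4 had 5.58 and 4.71, and 5.21 and 4.68 (others 6.14 to 6.46 and 5.68 to 5.9). Without control replicate 4, but with 1, GABAergic, glutamatergic and pan-neuronal medians were 0.23, 0.21 and 0.03, and macrophage and fibrotic scar medians -0.60 and -0.40. The immature neuron gene Dcx (0.48 ± 0.21) and the Notch genes Dll1 (0.43 ± 0.17) and Nrarp (0.44 ± 0.17) had edgeR adjusted p of 0.232, 0.22 and 0.208. Klf6 and Atf3 of the regeneration-associated list had log2 fold changes of -0.45 ± 0.17 and -0.87 ± 0.35 (SE). Camera called 16 of 38 lists (6 higher, 10 lower), with adjusted p of 2.98e-08 (macrophage), 1.86e-05 (complement and reactive astrocyte), 1.04e-05 (fibrotic scar and cholesterol) and 4.44e-06 (GABAergic). With an estimated correlation 0 were called, these 6 at an adjusted p of 0.52. EdgeR called 0 genes, with 3077 at an unadjusted p under 0.05 (816 by chance), DESeq2 14 and limma-voom 0. The 3077 became 1277 with the compared groups only, 1198 with Xist as a covariate, 1106 without the 2 libraries of mixed sex, 265 with the low-Xist libraries only, and 1513 and 1193 without injured control replicate 1 and 4. It was 5271 without injured control replicate 2, 4632 without Gsx1 replicate 3, and 1955, 1863 and 1850 without Gsx1 replicate 1, 2 and 4. Without injured control replicate 2 edgeR called 1872 genes, including 16 of the 23 named here (adjusted p 0.0258 to 0.048). With the low-Xist libraries only (2 controls) the macrophage median was -0.28. The change of the Gsx1 effect from 3 to 35 days was called for 0 genes (1614 at an unadjusted p under 0.05 in edgeR, 402 with the low-Xist libraries only, 0 called by DESeq2 and 0 by limma-voom). Without 1 library those 1614 ranged from 845 (injured control replicate 1 at 35 days) to 3480 (replicate 2).

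Nkx6.1 cords at 3 days differed from injured controls in 55 genes. The largest rises were Hfe (8.46 ± 1.71 to 27.2 ± 7.91 CPM), an iron regulator, the transporter Abcc3 (37.5 ± 15 to 105 ± 25.6), Adap2 (17.5 ± 5.19 to 42.1 ± 7.32) and Inpp5d (65.2 ± 11.4 to 147 ± 36.7), a phosphatase of blood cells (SD, n = 3 each). Rab3il1 and Zfand4 followed with log2 fold changes of 1.10 ± 0.24 and 1.09 ± 0.24 (SE). The largest falls were Ddn (dendrin, -2.96 ± 0.67), Pcdhb8 (-2.06 ± 0.47), Slc5a11 (-2.04 ± 0.37), the morphogen Shh (-1.67 ± 0.37), Itih3 (-1.52 ± 0.30) and Tdrd6 (-1.38 ± 0.29, log2, SE). These 12 had edgeR adjusted p of 0.0304 to 0.0486. In the astrocyte list 1 of 12 fell (5 alone; Ntsr2 from 109 ± 33.2 to 56.8 ± 2.89 CPM, SD, n = 3 each; median -0.32). In cholesterol synthesis 1 of 15 (12 alone; Cyp51 -0.75 ± 0.17, log2, SE; median -0.64). Camera adjusted p was 3.4e-05 and 3.62e-10, both 0.485 with an estimated correlation. In the macrophage list 0 of 20 were called and 10 rose adjusted over the list alone (median 1.08; Lyz2 1.57 ± 0.41, Apoe 1.24 ± 0.33, Ctsb 0.92 ± 0.24). Likewise 7 of 12 complement genes (median 0.96; C1qb 1.09 ± 0.37) and 7 of 12 microglia genes with 1 fall (median 0.59) rose on that count. Camera adjusted p of the 3 lists was 3.62e-10, 0.00145 and 0.000744. Cell cycle (median 0.67; Pcna 0.66 ± 0.23) lay higher and pan-neuronal (-0.40; Snap25 -0.69 ± 0.26), GABAergic (-0.59; Gad1 -0.83 ± 0.30) and myelin genes (-0.18; 3 fell alone; Fa2h -0.82 ± 0.19) lower, with camera adjusted p of 2.37e-05, 0.000136, 4.08e-06 and 0.00395. Each of these 7 had an adjusted p of 0.485 with an estimated correlation.

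Schwann cell genes were lower as a list at 3 days (1 rose and 6 fell adjusted over the list alone, median -1.18, camera adjusted p = 0.00218, 0.485 with an estimated correlation). The list means were 4.16 ± 0.5 in Nkx6.1 and 5.66 ± 0.86 log2 CPM in control libraries (SD, n = 3 each). Nkx6.1 replicate 2 held skeletal muscle genes at 5.55 mean log2 CPM, against -0.23 and -0.60 in replicates 1 and 3. EdgeR called 24 genes higher and 31 lower (2984 at an unadjusted p under 0.05), DESeq2 462 and limma-voom 4539 in total, and edgeR on the compared groups only 1. EdgeR called 160 with Xist as a covariate, 111 without the 2 libraries of mixed sex and 568 with the low-Xist libraries only. Trim12a was at its higher level in Nkx6.1 replicates 1 and 2 and in 0 of 3 controls. EdgeR called 4 genes with H2-Bl and Rpl29 as covariates and 2 with the level of Trim12a, and the 55 genes held a median of 88.8% and 87.3% of their log2 fold change (quartiles 83.1% to 96.1% and 81.3% to 92.2%). The 2984 genes became 1454 with the level of Trim12a and 1951 with H2-Bl and Rpl29 as covariates, 1660 without injured control replicate 2, 1511 without Nkx6.1 replicate 2, 5178 without Nkx6.1 replicate 3 and 6385 by limma-voom. The count was 2571 without Nkx6.1 replicate 3, 6 without its replicate 2 and 7 without its replicate 1, and 235, 0 and 0 without injured control replicate 1, 2 and 3. The calls of the 14 genes named (the 12 above, Ntsr2 and Cyp51) were therefore lost without injured control replicate 2 or 3 (adjusted p 0.103 to 0.331 and 0.141 to 0.254), and 13 each without Nkx6.1 replicate 1 or 2 (0.0696 to 0.165 and 0.0832 to 0.264). Without Nkx6.1 replicate 3, Lyz2, Apoe, Ctsb, Snap25, Gad1, C1qb, Fa2h, Pcna and Gja1 (-0.60 ± 0.15, adjusted p = 0.063) passed at 0.00172 to 0.0376, and Lyz2, Ctsb, Fa2h and Gja1 also passed without injured control replicate 1 (0.0319 to 0.0427).

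At 35 days Nkx6.1 cords had lower levels of the same phagocyte and complement lists, and no gene passed. Gpnmb stood at 199 ± 105 (SD, n = 3) against 577 ± 219 CPM (SD, n = 4) and Lyz2 at 406 ± 254 against 1020 ± 380. Ms4a7 (-1.54 ± 0.44), Serping1 (-1.37 ± 0.39) and Fn1 (-1.22 ± 0.39, log2, SE) also lay lower, and edgeR adjusted p of these 5 was 0.326 or 0.335. Adjusted over the list alone, 7 of 20 macrophage genes fell (median -0.84), 8 of 12 complement genes (-0.88) and 2 of 18 fibrotic scar genes (-0.95), with camera adjusted p of 1.61e-10, 5.05e-08 and 1.34e-05, 0.513, 0.513 and 0.556 with an estimated correlation. Neuronal lists lay higher: GABAergic (0.41; Gad2 0.75 ± 0.35), glutamatergic (0.37; Gria4 0.45 ± 0.20) and pan-neuronal (0.32), at camera adjusted p of 6.77e-06, 0.000332 and 6.77e-06, each 0.513 with an estimated correlation. With the low-Xist libraries only (2 controls) the macrophage median was -0.04 and Gad2 turned to -0.10. Without injured control replicate 4, but with replicate 1, GABAergic, glutamatergic and pan-neuronal medians were 0.18, 0.24 and 0.15, and that of the fibrotic scar list -0.22. Of 7 immature neuron genes 1 rose alone (Dcx 0.65 ± 0.22), and of 23 Notch genes 2 fell alone (Notch2 -0.53 ± 0.16, Hey2 -0.51 ± 0.16). EdgeR and DESeq2 called 0 genes (2006 at an unadjusted p under 0.05 in edgeR, 816 by chance) and limma-voom 185. The 2006 became 539 with the compared groups only, 740 without the 2 libraries of mixed sex, 1096 each with the low-Xist libraries only and with H2-Bl and Rpl29 as covariates, 1120 with the replicate block, and 766 without injured control replicate 4. It was 3875 without injured control replicate 2, 952, 858 and 3410 without Nkx6.1 replicate 1, 2 and 3, and 3296 by limma-voom. EdgeR called 72 without Nkx6.1 replicate 3, with Lyz2, Serping1 and Dcx at an adjusted p of 0.0484, 7 without injured control replicate 1, and 1 with the compared groups only.

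The change of the Nkx6.1 effect from 3 to 35 days was tested as an interaction, and 376 genes were called (71 higher, 305 lower, 4266 at an unadjusted p under 0.05). Among the lower genes were Wfdc17 (-3.92 ± 0.98), the RNA sensor Tlr8 (-3.82 ± 0.94), Cd244 (-3.73 ± 0.94) and Kynu (-3.43 ± 0.94). Higher were Ddn (3.16 ± 0.86), Gadl1 (2.50 ± 0.66), Pcdhb8 (2.44 ± 0.62) and Foxb1 (2.36 ± 0.59, log2, SE), with edgeR adjusted p of 0.0426 to 0.0496 over the 8. Of 20 macrophage genes 10 fell (15 adjusted over the list alone), with a median of -1.95, a camera adjusted p of 4.66e-14, 0.461 with an estimated correlation, and 0.0326 by fry. Of 15 cholesterol synthesis genes 1 rose (12 alone, median 0.80, camera adjusted p = 4.42e-08, 0.461 with an estimated correlation). The count was 1265 with DESeq2 and 4412 with limma-voom, 826 with Xist as a covariate, and 0 with the compared groups only, without the 2 libraries of mixed sex, with the low-Xist libraries only, and with H2-Bl and Rpl29 or the level of Trim12a as covariates. It was 724, 0 and 0 without injured control replicate 1, 2 and 3 at 3 days, and 0, 0 and 3614 without Nkx6.1 replicate 1, 2 and 3 at 3 days. It was 0, 2315, 672 and 0 without injured control replicate 1, 2, 3 and 4 at 35 days, and 0, 0 and 1924 without Nkx6.1 replicate 1, 2 and 3 at 35 days. The adjusted p of the 8 genes lay between 0.0664 and 0.167 without each of the 8 libraries at which the count was 0, and that of Kynu was 0.0591 without injured control replicate 1 at 3 days.

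The 2 factors were also compared directly. At 3 days 13 genes differed (11 higher and 2 lower in Gsx1 cords, 2311 at an unadjusted p under 0.05). Slc5a11 was 6.18 ± 2.14 in Gsx1 against 1.68 ± 0.942 CPM in Nkx6.1 libraries, the peptide transporter Slc15a2 28.6 ± 6.32 against 11.8 ± 1.54, Tst 46.3 ± 11.1 against 21.5 ± 1, and the mitochondrial carrier Slc25a18 90.5 ± 25.7 against 45.1 ± 2.47. Lower in Gsx1 were Zfand4 (log2 fold change -1.22 ± 0.24 SE) and the ectoenzyme Cd38 (61.5 ± 11.2 against 109 ± 9.39, SD, n = 3 each), all 6 with edgeR adjusted p of 0.0119 to 0.0354. Nkx6-1 itself had a log2 fold change of 0.57 ± 0.23 (SE, edgeR adjusted p = 0.281). Astrocyte genes were higher in Gsx1 cords (1 of 12 rose, 4 alone, median 0.39, camera adjusted p = 5.01e-07, 0.121 with an estimated correlation, fry 0.00536), and macrophage genes lower (0 of 20, 1 fell alone, median -0.72, camera adjusted p = 5.01e-07, 0.506 with an estimated correlation). Skeletal muscle genes (10 of 11 fell alone, median -5.4, camera adjusted p = 0.00135, 0.506 with an estimated correlation) followed Nkx6.1 replicate 2. DESeq2 called 135 genes, limma-voom 5185, and edgeR 0 on the compared groups only, 7 with H2-Bl and Rpl29 as covariates and 3 with the level of Trim12a, which was higher in Gsx1 replicate 1 and Nkx6.1 replicates 1 and 2. Without Gsx1 replicate 1, 2 and 3 the count was 554, 0 and 0, and without Nkx6.1 replicate 1, 2 and 3 it was 1, 0 and 1942. The 6 genes named lost their calls without Gsx1 replicate 2 or 3 or Nkx6.1 replicate 1 or 2 (adjusted p 0.0551 to 0.653). At 35 days edgeR called 0 genes (393 at an unadjusted p under 0.05), DESeq2 0 and limma-voom 1056, and camera 6 of 38 lists, among them myelin (0 of 13, median 0.20, adjusted p = 3.07e-05) and skeletal muscle (0 of 11, median -2.84, 3.2e-06), both 0.837 with an estimated correlation.

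Fold changes across the 16314 genes were correlated between comparisons, to show whether the factors moved genes along or against the injury response. Genes are not independent replicates, and the shared control libraries give a correlation without any effect, so the simulated value stands beside each. At 3 days the effects of Gsx1 and Nkx6.1 had r = 0.44 (simulated 0.51, covariance 0.0996 against 0.0786), Gsx1 and injury r = -0.18 (simulated -0.50, covariance -0.0804 against -0.0778), and Nkx6.1 and injury r = 0.32 (simulated -0.50, covariance 0.189 against -0.0782). At 35 days Gsx1 and Nkx6.1 had r = 0.69 (simulated 0.47, covariance 0.144 against 0.056), Gsx1 and injury r = -0.68 (simulated -0.46, covariance -0.332 against -0.056), and Nkx6.1 and injury r = -0.69 (simulated -0.42, covariance -0.357 against -0.0563). The covariance less its simulated value was 0.021, -0.00254 and 0.267 at 3 days and 0.0885, -0.276 and -0.301 at 35 days. The sign was shared by 64.8%, 50.4% and 70% of genes at 3 days (simulated 66.8%, 33.3% and 33.3%) and by 80.5%, 19.6% and 18.1% at 35 days (simulated 65.5%, 34.7% and 36%). With the 4 controls of 35 days split into separate pairs for the 2 comparisons, r was 0 to 0.34 for Gsx1 and Nkx6.1, -0.57 to -0.24 for Gsx1 and injury, and -0.56 to -0.19 for Nkx6.1 and injury over 6 splits. The 3-day groups held too few controls to split, so part of the excess for Gsx1 and Nkx6.1 there may come from the shared controls. For Nkx6.1 and injury the shared controls act against the sign seen. At 3 days the r of Gsx1 and Nkx6.1 was 0.15 without Gsx1 replicate 1 and 0.62 without Nkx6.1 replicate 2. That of Gsx1 and injury was -0.31 without Gsx1 replicate 1, -0.05 without Gsx1 replicate 3 and -0.33 without injured control replicate 2. That of Nkx6.1 and injury was 0.17 and 0.19 without injured control replicate 2 and 3 and 0.09 without Nkx6.1 replicate 2, and it turned to -0.04 without the expression filter. Of the genes called for Nkx6.1 at 3 days, 13 of 24 higher and 6 of 31 lower ones were called in the same direction by injury (4.7 and 5 for independent lists), and 0 and 0 in the opposite one (3.8 and 6). Lists simulated without effects gave 0 and 0 in the same and 19.9 and 23.1 in the opposite direction. They are no baseline for real injury lists.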

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

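The tests in this part were all fixed before their results were seen. Outlying samples were sought in the 2 groups of 4 libraries over 78 values, by the gap to the nearest library as a share of the range set against Dixon's 95% critical value. Chance gives about 1 in 20, and 9 values passed.

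Injured control replicate 4 at 35 days stood apart in 2 gene lists. Its pan-neuronal mean was lowest (8.26 log2 CPM, others 9.07 to 9.16, gap share 0.9) and its type I interferon mean highest (4.14, others 2.92 to 3.11, gap share 0.846). This library also held both Xist and Y-linked reads.

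Gsx1 replicate 3 at 35 days stood apart in 6 lists. It was highest for neural stem genes (4.29 against 3.88 to 3.93, gap share 0.862). It was lowest for glutamatergic genes (5.3 against 5.85 to 5.91, 0.898), GABAergic and glycinergic genes (5.85 against 6.46 to 6.51, 0.926), axon guidance genes (5.26 against 5.69 to 5.72, 0.923), neurotrophic factors (3.63 against 4.01 to 4.07, 0.862) and chondroitin sulfate proteoglycans (5.16 against 5.69 to 5.73, 0.935). Gsx1 replicate 1 at 35 days was highest for red blood cell genes (5.94 against 3.65 to 3.75, gap share 0.955).

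Effects that differed between times were taken from the interaction tests. The injury effect differed between 35 and 3 days for 59 genes, among them Slc47a1 (7.10), Igf2 (4.33), Clec3b (4.15), Fmod (3.85), Cep55 (-5.07), Cdca5 (-4.57), Kif14 (-3.74) and Ckap2 (-3.38, log2). The Nkx6.1 effect differed for 376 genes, among them Ddn (3.16), Gadl1 (2.50), Pcdhb8 (2.44), Foxb1 (2.36), Wfdc17 (-3.92), Tlr8 (-3.82), Cd244 (-3.73) and Kynu (-3.43, log2). Leaving out 1 library moved the count of 59 to between 12 (sham replicate 1 at 35 days) and 99 (injured control replicate 1 at 35 days). It moved the count of 376 to between 0 and 3614 (Nkx6.1 replicate 3 at 3 days).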

How the results depend on the processing

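The settings without mixed-sex libraries or with low-Xist ones only were chosen after seeing the data. So were H2-Bl and Rpl29 or the level of Trim12a as covariates. RLE and upper-quartile factors and the strict filter moved no count of called genes by over 1.5 times, and other settings moved counts in both directions. The low-Xist libraries include 1 sham library at 3 days, which is assumed to vary like the other groups. For alternatives with fewer libraries or with a stricter threshold, the change in construction accounts for at least part of a lower count. For the others the cause was not tested. List members called after injury were counted again in the 4 settings chosen after seeing the data. List medians at 35 days were taken again without injured control replicate 4, also after seeing the data. Of the values for named genes, 2292 kept their direction and side of the threshold under other settings and 1147 without 1 library, 227 and 225 fell short of the threshold, 45 and 34 came to pass it, and 8 and 7 reversed.

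Counts of called genes moved by over 1.5 times as follows. Injury at 3 days (5788): low-Xist libraries 1753, at least 2-fold 2163, adjusted p under 0.01 3448. Injury at 35 days (6009): compared groups only 2195, without mixed-sex libraries 3178, low-Xist libraries 1281, H2-Bl and Rpl29 covariates 3666, at least 2-fold 2084, adjusted p under 0.01 3187. Gsx1 at 14 days (0): no filter 3, DESeq2 47, limma-voom 423, compared groups only 29, without mixed-sex libraries 17, low-Xist libraries 42, H2-Bl and Rpl29 covariates 7, Trim12a level 7. Gsx1 at 35 days (0): DESeq2 14. Nkx6.1 at 3 days (55): no filter 28, DESeq2 462, limma-voom 4539, compared groups only 1, Xist covariate 160, without mixed-sex libraries 111, low-Xist libraries 568, H2-Bl and Rpl29 covariates 4, Trim12a level 2, at least 2-fold 18, adjusted p under 0.01 1. Nkx6.1 at 35 days (0): limma-voom 185, compared groups only 1. Gsx1 against Nkx6.1 at 3 days (13): DESeq2 135, limma-voom 5185, compared groups only 0, H2-Bl and Rpl29 covariates 7, Trim12a level 3, at least 2-fold 5, adjusted p under 0.01 0. Gsx1 against Nkx6.1 at 35 days (0): limma-voom 1056.

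Injured control at 35 against 3 days (1797): limma-voom 3202, compared groups only 457, low-Xist libraries 331, at least 2-fold 687, adjusted p under 0.01 666. Sham at 35 against 3 days (1): DESeq2 41, limma-voom 426, compared groups only 633, Xist covariate 0, without mixed-sex libraries 3, low-Xist libraries 0, H2-Bl and Rpl29 covariates 5, Trim12a level 12, adjusted p under 0.01 0. Injury by time (59): DESeq2 230, limma-voom 565, compared groups only 32, Xist covariate 18, without mixed-sex libraries 10, low-Xist libraries 1, H2-Bl and Rpl29 covariates 169, Trim12a level 108, adjusted p under 0.01 7. Gsx1 by time at 14 days (0): DESeq2 2. Nkx6.1 by time (376): no filter 224, DESeq2 1265, limma-voom 4412, Xist covariate 826, and 0 with the compared groups only, without mixed-sex libraries, with low-Xist libraries, with the H2-Bl and Rpl29 covariates, with the Trim12a level and at an adjusted p under 0.01.

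The replicate block used replicate numbers that do not pair the libraries by the check of pairing. Deviations from group means of same-numbered libraries had a median correlation of -0.002 (other numbers -0.008), 28 of 136 same-numbered pairs lay over 0.1, and 8 of 32 libraries correlated best with their own number. With the block, counts became 2 for Gsx1 at 14 days, 105 for Nkx6.1 at 3 days, 2 for sham over time, 20 for injury by time and 33 for Nkx6.1 by time.

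Gene list counts by camera with an estimated correlation, against 20 and 22 for injury at 3 and 35 days, were 1 and 3, and fry gave 24 and 25. Against 10, 10 and 16 for Gsx1 at 3, 14 and 35 days they were 0, 1 and 0, and fry gave 0, 1 and 0. Against 16 and 15 for Nkx6.1 at 3 and 35 days they were 0 and 0 (fry 1 and 0), and against 18 and 6 for Gsx1 against Nkx6.1 they were 0 and 0 (fry 1 and 0). For time in injured control (14) and sham cords (15) they were 1 and 1, and fry gave 11 and 1.

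The r of Gsx1 with injury at 3 days (-0.18) was -0.33 with no filter and -0.05 with the compared groups only. That of Nkx6.1 with injury at 3 days (0.32) reversed to -0.04 with no filter and was 0.44 with the compared groups only. At 35 days, Gsx1 with Nkx6.1 (0.69) was 0.59 and 0.76, Gsx1 with injury (-0.68) -0.56 and -0.76 in these settings, and Nkx6.1 with injury (-0.69) -0.55 with no filter.

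Without 1 library, counts ranged from 3530 to 5462 (injury 3 days), 3453 to 7043 (injury 35 days), 0 to 11 (Gsx1 14 days), 0 to 1872 (Gsx1 35 days), 0 to 2571 (Nkx6.1 3 days), 0 to 72 (Nkx6.1 35 days), 0 to 1942 (Gsx1 against Nkx6.1, 3 days), 797 to 2331 (injured control over time), 0 to 4 (sham over time), 12 to 99 (injury by time), 0 to 2 (Gsx1 by time at 14 days) and 0 to 3614 (Nkx6.1 by time). They stayed at 0 for Gsx1 at 3 days, Gsx1 against Nkx6.1 at 35 days and Gsx1 by time at 35 days. The r ranged from 0.15 to 0.62 (Gsx1 and Nkx6.1), -0.33 to -0.05 (Gsx1 and injury) and 0.09 to 0.39 (Nkx6.1 and injury) at 3 days, and from 0.55 to 0.78, -0.73 to -0.5 and -0.77 to -0.52 at 35 days.

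Nkx6-1 after injury at 3 days (-0.01) was 0.01 with no filter, the strict one or the Trim12a level and 0 with the compared groups only or the low-Xist libraries, and ranged from -0.12 to 0.08 without 1 library. In Gsx1 cords at 3 days (-0.04) it ranged from -0.23 to 0.09 without 1 library. For Nkx6.1 at 35 days, Nkx6-1 (-0.20) became 0.06 and Gad2 (0.75) became -0.10 with the low-Xist libraries. Trim12a itself in injured controls over time (5.41) became -0.07 with its own level as a covariate, as the covariate takes up its difference. Depth limits Gsx1 itself, which had 0 to 10 counts per library.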

Other observations

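The low-Xist libraries, the covariates, the tests on Trim12a and on the Gsx1 libraries of 3 days alone, and the use of component 1 and of shared calls against chance were chosen after seeing the data, and the other tests here were fixed before their result was seen.

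Several lists moved in ways not described above. In Gsx1 against Nkx6.1 cords at 3 days, dorsal spinal transcription factors had a median log2 fold change of 0.75 (0 of 11 passed) and type I interferon genes of 0.78 (0 of 20 passed), with camera adjusted p of 7.89e-05 and 3.88e-05, both 0.506 with an estimated correlation. In sham cords, pericyte and smooth muscle genes lay lower at 35 than at 3 days (0 of 8 passed, 2 fell adjusted over the list alone, median -0.68, camera adjusted p = 4.52e-06, 0.109 with an estimated correlation), as did Schwann cell genes (0 of 10, 3 alone, median -0.90, camera adjusted p = 1.26e-05, 0.266 with an estimated correlation).

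Genes called for Nkx6.1 at 3 days were weighed against genetic background, with H2-Bl and Trim12a as markers, and lesion tissue in the segment, with the macrophage list as its measure. Slopes within the other 8 groups predicted 10.6% of the observed change from H2-Bl (5.39% to 12.7% leaving out each group), 13.7% from the level of Trim12a (6.23% to 16.2%) and 19% from the macrophage list (10.8% to 23%), under the bound of 25% set to exclude each as the whole cause. That bound assumed equal slopes at all times, and the Gsx1 libraries, the only other injured ones at 3 days, predicted 33%, 41.6% and 69.6% alone, so with 3 libraries none is excluded. With H2-Bl and Rpl29 or the level of Trim12a as covariates 4 and 2 genes were called, and all 55 held their direction. The median absolute log2 fold change went from 0.75 to 0.66 at a median SE of 0.16 in all fits. Adjusted p reached 0.167 and 0.264, and why calls ended was not tested. Background and lesion tissue may each contribute, and an effect of Nkx6.1 stays open and was not tested apart from them.

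The lower macrophage list in both factor groups at 35 days rests on 4 shared control libraries. Against pairs of these controls the 12 medians ran from -1.32 to -0.28, so none reached 0. The highest lay short of the bound of -0.3 set to exclude chance values of the controls. With the low-Xist libraries only the median was -0.28 for Gsx1 and -0.04 for Nkx6.1, and with 2 controls sex cannot be told from treatment. Either, or the cord level (untested), may account for it, and an effect of the factors stays open.

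Of the genes tested, 14 lay at separate levels within at least 3 groups, among them Trim12a, Ifi202b, Hal, Bfsp2, Sycp1 and Rec8. Their median absolute correlation with Xist was 0.1, which excludes sex as the cause. DNA variants between mice may explain them, though the labels name 1 strain. Picked after seeing values, Trim12a, 2610507I01Rik and Gpr137b-ps (chromosomes 7, 11 and 13) had the same levels in all 32 libraries. BC002163 (chromosome 16) had the reverse, so a shared background stays open too. Rpl29 was at 11.1 to 17.9 CPM where Bfsp2, within 5 Mb, was low and at least 45.8 elsewhere. Within 5 Mb lay 1 pair of the 14, Hoxc12 and Hoxc13 (absolute correlation 0.47 above the 87 pairs on other chromosomes). These Hox genes follow the cord level and decide nothing about variants. Tissue taken stays open, untested, for them, Arg1 and Myh4 (macrophages, muscle).

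Other splits of the compared libraries were refitted to see what chance gives. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 5788 and 0 for injury at 3 days, 0 and 1 for Gsx1 at 3 days, 0 and 2 for Gsx1 at 14 days, 55 and 1211 for Nkx6.1 at 3 days, 13 and 3762 for Gsx1 against Nkx6.1 at 3 days, and 1 and 0 for sham over time. With 35 splits, 2 were as large as the real one for injury at 35 days, itself included (6009, highest other 6459). The other set the 3 sham libraries and injured control replicate 2 against the other 3 controls, so it held most of the injury contrast. Chance is excluded there by component 1, which placed the 6 sham libraries at -91.9 to -64.3 and the 26 injured ones at -42 to 103.9. Of the calls, 2193 higher and 1665 lower ones were shared with injury at 3 days, from separate libraries, and 10 were opposite. Chance was not excluded by the splits for injured controls over time (1797, highest other 2234, 3 splits as large). For Gsx1, Nkx6.1 and Gsx1 against Nkx6.1 at 35 days the real count was 0, which all 35 splits reach, so their number decides nothing (highest other 4619, 4387 and 1). For the list counts chance was not excluded for Gsx1 (16, highest other 18, 5 splits as large) or Nkx6.1 at 35 days (15, highest other 22, 12 splits as large). Splits that called 1211 and 3762 genes, several times the real count, and those that called 4619 and 4387 where it was 0 point to a structure of the samples other than the groups. The split of 3762 set Gsx1 replicate 1 and Nkx6.1 replicates 1 and 2, all at the higher level of Trim12a, against the other 3 libraries, all at the lower one. The split of 1211 set injured control replicate 1 and the same 2 Nkx6.1 libraries against the rest. The split of 4619 fell within libraries all at the higher level, and that of 4387 set 3 of 3 against 3 of 4 at that level.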
